A study of Mus musculus with 8 samples.

How the data were processed

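Nuclei were isolated from the striatum of C57BL/6 mice, sorted on the DNA stain DAPI and loaded on the 10x Genomics droplet platform, per the labels' protocols, and the RNA was sequenced as single-nucleus libraries with molecular identifiers (UMIs). The 8 libraries used fall into 4 groups of 2: mice with the usual specific-pathogen-free flora (SPF) at rest, mice given broad-spectrum antibiotics at rest, SPF mice after exercise, and antibiotic-treated mice after exercise. The kind, length and time of the exercise, the antibiotics and the sex of the mice are not given in the sources used here. No label says that the libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be partly technical.

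The deposited values are raw UMI counts per gene and barcode, made with Cell Ranger, version 3 per the submitters' processing notes and 3.1.0 per the file headers. The genome build was mm10, per the submitters' processing notes. The authors' files hold 31053 genes in the same order in every library. Of the gene identifiers, 30934 were found in the GENCODE vM21 annotation (GRCm38), from which the positions in the text were taken. Whether intronic reads were counted is not given in the sources used here. Counts per gene include molecules that cannot be assigned between near-identical copies, so values of ribosomal protein genes, which have many processed pseudogenes, are uncertain for any single gene and are described as a group.

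Nuclei with at least 500 UMIs, at least 200 genes and at most 5% mitochondrial UMIs were kept. Doublets were scored with Scrublet as built into scanpy 1.11.5. The nuclei with the highest scores, a share of 0.008 per 1000 nuclei in the library (3.44% to 6.50%), were called doublets and left out of all sums. The 8 libraries were clustered together on 2000 variable genes, 30 principal components and 20 neighbours with leidenalg 0.10.2 at a resolution of 1.0 and seed 1, in Python 3.11.15. Each variable gene was first centred and scaled within each library. This takes shifts of whole libraries out of the clustering and depends on each library's own mix of nuclei. Clusters were named from marker genes fixed before the data were examined. A name needed at least 3 markers of the type that were detected in 10% of the nuclei at 1.5 times the level elsewhere, and a score of at least 0.5. Clusters of fewer than 20 nuclei, clusters with over 50% called doublets and clusters that met no name stayed unnamed. So did clusters with a median under 0.333 times the UMIs of their libraries and no marker of the type among their top 10 genes, and clusters with more top genes of another type. A name such as D1 medium spiny neuron therefore means nuclei that look like that type by these markers.

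Counts were summed per library and class in 5 classes: D1 and D2 medium spiny neurons (the striatal projection neurons that carry the dopamine receptors Drd1 and Drd2), astrocytes, oligodendrocytes and microglia. Each class was fitted with edgeR 4.0.16 in R 4.3.3: TMM normalization, the package's filter on low counts by group, 1 mean per group, and quasi-likelihood tests with 4 residual degrees of freedom. The spread of each gene was drawn toward that of all genes of the class. The prior degrees of freedom ran from 21 in D1 neurons to 68 in microglia. A p-value thus rests largely on the spread shared between genes. The 5 contrasts tested in each class were exercise in SPF mice, exercise in antibiotic-treated mice, antibiotics at rest, antibiotics after exercise, and the difference of both exercise effects (antibiotics minus SPF). P-values were adjusted by Benjamini-Hochberg over the genes tested in a class and contrast, with a threshold of 0.05. Log2 fold changes are given with their standard error (SE), levels as CPM within the class with the SD of the libraries of a group (n = 2).

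Gene lists were tested on log2 CPM with camera (limma 3.58.1) at a preset correlation of 0.01, two-sided, and beside it with an estimated correlation and with fry; adjusted p-values cover the lists tested in a class and contrast. A list needed at least 3 tested members. The 30 lists were immediate early genes, late activity-regulated genes, dopamine synthesis and breakdown, dopamine receptor signalling, striatal neuropeptides and opioid receptors, the endocannabinoid system, glucocorticoid response, circadian clock, heat shock, unfolded protein response, cholesterol synthesis, interferon response and MHC class I, homeostatic microglia, activated microglia, reactive astrocytes, astrocyte functions, myelin, oxidative phosphorylation, glycolysis and lactate handling, glutamate receptors, GABA receptors and transport, voltage-gated potassium channels, cytoplasmic ribosomal proteins, mitochondrially encoded genes, nuclear long non-coding RNAs, free RNA of striatal neurons, blood cells, choroid plexus, cortical glutamatergic neurons and sex-linked transcripts. The last 5, with the lists of the other classes, stand for RNA of other cells or for the make-up of the samples. Some genes are in more than 1 list, such as Per1, an immediate early gene and a clock gene.

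The groups, contrasts, gene lists, tests and rule for named genes were fixed at the same stage. The rule took, per contrast and class, up to 3 higher and 3 lower genes with the largest change among those that passed, had a mean of at least 30 CPM in the higher group and did not overlap between the groups compared, leaving out clone names, mitochondrially encoded and ribosomal protein genes. It added, per list described, up to 4 members with the lowest p-value among those that passed adjusted over the list alone, or else up to 2 as values, and in both neuron classes a fixed set of early genes, dopamine and cannabinoid genes and the glucocorticoid-response genes Fkbp5 and Sgk1. Not every gene the rule takes is printed, and a few genes are not reported here.

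Class shares were computed among all nuclei kept and compared between 4 and 4 libraries with an exact two-sided permutation test over 70 splits (scipy 1.17.1), whose smallest p is 0.0286. With 2 against 2 libraries it cannot go below 0.333, so those shares are given as values.

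Each fit was tested on simulated counts with 200 genes changed by known amounts. For antibiotics at rest, the share of genes recovered at log2 changes of 0.5, 1 and 2 was 31.3%, 73.1% and 95.5% in D1 neurons, 23.9%, 71.6% and 92.4% in D2 neurons, 7.46%, 49.3% and 87.9% in astrocytes, 10.4%, 56.7% and 90.9% in oligodendrocytes, and 5.97%, 47.8% and 83.3% in microglia. Wrong calls made up 0.943% to 7.69% of the calls. The simulated counts held no shift of whole libraries and no correlation between genes, so these shares need not hold for the real calls.

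Alternatives fixed with the tests were another normalization (RLE size factors), no filter on low counts, the replicate number as a block, doublets kept, sums thinned to the lowest total of the class, each library left out in turn, DESeq2 1.42.0 in place of edgeR, both other list tests, and for the shares a clustering resolution of 1.5 and a minimum of 1000 UMIs. Added after the data had been seen were a fit of the D1-minus-D2 difference of each contrast in both neuron classes with the library as a block, a repeat in nuclei with under 0.1% mitochondrial UMIs, repeats within single D1 and oligodendrocyte clusters, and a night-minus-day score of clock genes.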

Results

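The transcripts of single nuclei were measured in the striatum of mice with normal gut flora (specific-pathogen-free, SPF) and of mice whose flora was depleted with antibiotics, at rest and after exercise, with 2 libraries in each of the 4 groups. The study asked how the microbiome acts on the motivation for exercise. The striatum receives dopamine from the midbrain, and its 2 kinds of projection neurons, D1 and D2 medium spiny neurons, carry the receptors Drd1 and Drd2. Of 4087 to 8280 barcodes per library 3934 to 7521 nuclei were kept. Before called doublets were left out, the median per nucleus was 2430 to 3848 UMIs. Fold changes are log2 values with their SE from edgeR's quasi-likelihood test over all 8 libraries, levels are CPM with the SD of 2 libraries, and adjusted p-values are those of Benjamini-Hochberg.

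The rest and the exercise libraries differed in RNA composition in every nucleus class. The median mitochondrial share per nucleus was 0.428% to 0.579% in the 4 rest libraries and 0.0152% to 0.0278% in the 4 exercise libraries. Malat1, a long RNA retained in the nucleus, took 7.93% to 10.8% of the UMIs at rest and 11.5% to 12.8% after exercise. Gm42418, a transcript that overlaps ribosomal RNA, lay at 2109 and 2084 CPM with antibiotics at rest, 1361 and 1192 CPM in SPF mice at rest and 417 to 556 CPM after exercise. Hbb-bs, a beta-globin of red blood cells, stood at 27 and 40.1 CPM in SPF mice at rest, 9.12 and 9.66 CPM with antibiotics at rest, and 1.2 to 1.93 CPM in the exercise libraries. The blood cell list had 4 tested members in the fit of both neuron classes given below, and its tests within single classes are not reported here. No library of one state lay inside the range of the other for these 4 measures, so every exercise effect below is also a comparison of libraries that differ in this way.

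**Figure D1:**
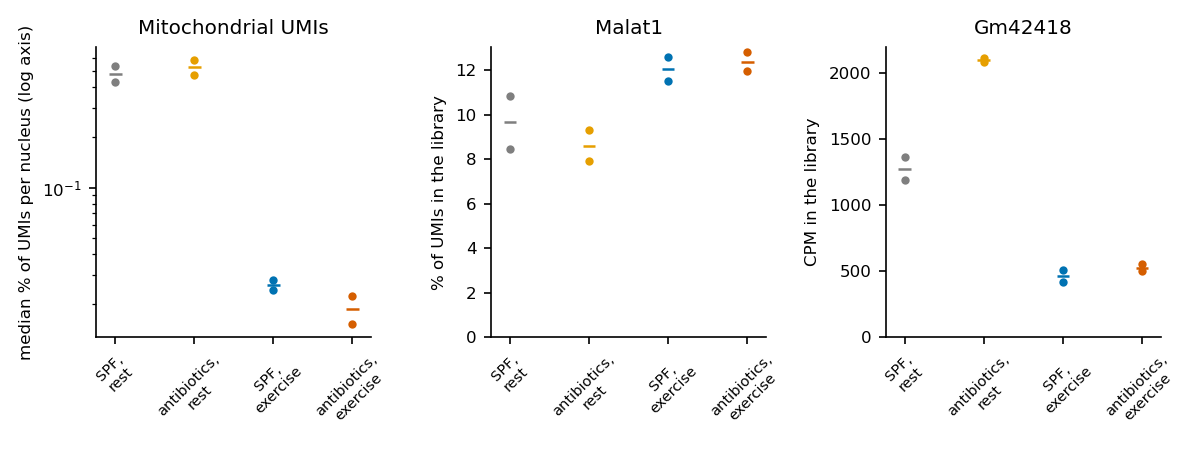
Median mitochondrial share of UMIs per nucleus (percent, log axis), Malat1 share of UMIs (percent) and Gm42418 level (CPM) in each of the 8 libraries, by group; points are libraries and lines are group means. The 4 exercise libraries lie at 0.0152% to 0.0278% mitochondrial UMIs and the 4 rest libraries at 0.428% to 0.579%.

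D1 neurons made up 25.3% to 30.5% of the nuclei in the group means and D2 neurons 19.0% to 22.9%. Oligodendrocytes were 12.1% and 12.4% of the nuclei in SPF and antibiotic-treated mice at rest and 16.9% and 17.9% after exercise. That difference of 5.11 percentage points had an exact permutation p of 0.0286, the smallest that 4 against 4 libraries can give, and an adjusted p of 0.114 over 16 classes. Astrocytes ranged widely after exercise, with 5.68% ± 1.07 (SD, n = 2) in SPF mice against 10.0% and 18.6% in both libraries of antibiotic-treated mice. No class passed the adjusted test for exercise or for antibiotics. With 0.0286 as the smallest p and 16 classes, a class could not have passed by itself. The failure to pass thus says little. The direction of the oligodendrocyte difference turned at the higher clustering resolution, with 12.1% and 11.1% in SPF and antibiotic-treated mice at rest and 6.88% and 7.80% after exercise. There a cluster of 2078 nuclei that scored highest for oligodendrocytes, with a median of 866 UMIs and 0.089% mitochondrial UMIs, stayed unnamed. Among nuclei of at least 1000 UMIs the shares were 11.9% and 9.46% at rest and 8.93% and 11.2% after exercise, so the direction turned in SPF mice. Clusters left unnamed for reasons other than doublets or size held 12.1% to 16.2% of the nuclei in the group means. Clusters of mostly called doublets held up to 0.54% more, and those under 20 nuclei up to 0.054%.

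**Figure D2:**
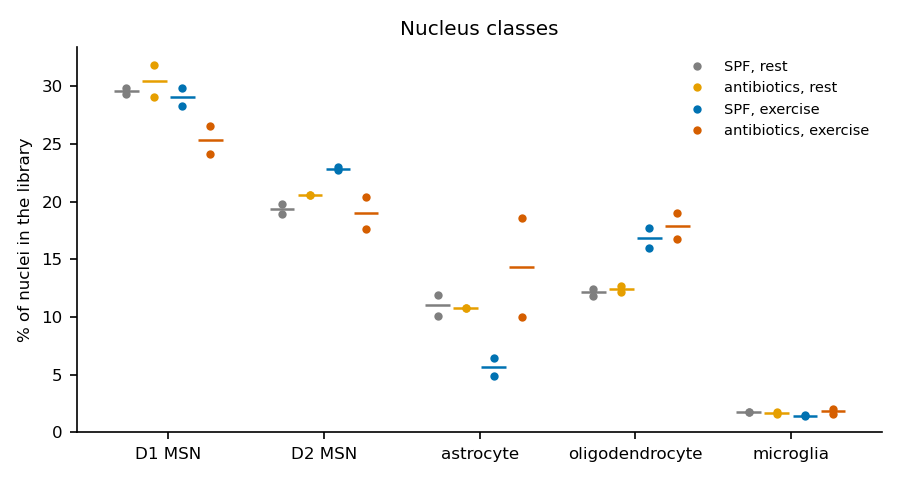
Share of each library's nuclei (percent) named as D1 neurons, D2 neurons, astrocytes, oligodendrocytes or microglia, by group; points are libraries and lines are group means. Astrocytes made up 10.0% and 18.6% of the nuclei in the antibiotic-treated exercise libraries and a mean of 5.68% in the SPF exercise libraries.

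Exercise in SPF mice raised the immediate early genes of D1 neurons, which are transcribed within minutes of neuronal activity. Arc, a regulator of synaptic AMPA receptors, rose from 17.7 ± 2.45 to 82.8 ± 9.59 CPM (log2 2.22 ± 0.163, adjusted p = 3.25e-10). The transcription factor genes Junb (2.06 ± 0.233), Fosb (1.92 ± 0.336), Nr4a1 (1.91 ± 0.125), Egr1 (1.87 ± 0.148) and Fos (1.67 ± 0.236) rose as well. Npas4 (0.51) passed adjusted over the list alone and not over all genes (adjusted p = 0.1). Of 25 early genes tested, 19 rose and none fell adjusted over the list alone, and 18 rose over all genes tested. The list's median was 1.52 and its adjusted p in camera was 5.47e-14, against 0.282 with an estimated correlation. Among late activity-regulated genes 17 of 22 rose and 1 fell adjusted over the list alone (14 and 0 over all genes), led by Spred1 (1.90 ± 0.122), the kinase gene Plk2 and the synaptic scaffold gene Homer1 (337 ± 24.2 to 751 ± 79.3 CPM). That list's adjusted p was 4.17e-09, and 0.115 with an estimated correlation.

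These genes lie on the mouse genome (GRCm38) at chromosome 15, 74669083 to 74672570, for Arc (ENSMUSG00000022602), chromosome 18, 34859823 to 34864984, for Egr1 (ENSMUSG00000038418), chromosome 12, 85473890 to 85477273, for Fos (ENSMUSG00000021250), chromosome 8, 84974484 to 84978718, for Junb (ENSMUSG00000052837), chromosome 15, 101254269 to 101274795, for Nr4a1 (ENSMUSG00000023034), and chromosome 13, 93299635 to 93405129, for Homer1. All are protein-coding.

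Other groups of D1 neurons moved with exercise in SPF mice. Dopamine receptor signalling genes rose in 18 of 32 and fell in 2 adjusted over the list alone (15 and 2 over all genes; adjusted p = 0.000318, and 0.282 with an estimated correlation), with the phosphodiesterase genes Pde1c (0.88 ± 0.11), Pde4b (0.67 ± 0.126) and Pde7b (0.61 ± 0.118). Clock genes rose in 11 of 21 and fell in 1 (10 and 1 over all genes; adjusted p = 4.92e-06, and 0.282 with an estimated correlation), among them the early gene Per1 (1.76 ± 0.116), Bhlhe40 (2.13 ± 0.21) and Per2 (1.33 ± 0.142). In dopamine synthesis and breakdown, 1 of 11 rose and 3 fell adjusted over the list alone (1 and 2 over all genes; adjusted p = 0.252). Qdpr, which recycles the cofactor of dopamine synthesis, fell by 1.21 ± 0.25. Maoa, whose product breaks dopamine down, was at 0.18 ± 0.185 (adjusted p = 0.529). Glutamate receptor genes rose in 6 of 22, adjusted over the list alone and over all genes (adjusted p = 0.0464, and 0.63 with an estimated correlation). Among the genes taken for the size of their change, rises were seen in Dnaja2, a co-chaperone (2.56 ± 0.127), Pdp1, which activates pyruvate dehydrogenase (2.50 ± 0.126), and the ubiquitin-conjugating enzyme gene Ube2j1 (2.25 ± 0.185). Cst3 (-2.49 ± 0.15) and Apoe (-2.04 ± 0.153), both abundant in glia, and the ferritin gene Fth1 (-1.58 ± 0.132) fell.

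Transcripts that are mostly cytoplasmic fell in the same D1 nuclei, whose libraries held fewer mitochondrial UMIs. All 13 mitochondrially encoded genes fell, adjusted over the list alone and over all genes, with a median of -3.33 (mt-Co2, -3.38 ± 0.124, and mt-Atp6, -3.73 ± 0.15). Of 75 genes of cytoplasmic ribosomal proteins 62 fell and 1 rose adjusted over the list alone (58 and 0 over all genes; median -1.07), and of 71 nuclear genes of oxidative phosphorylation 48 fell (38 over all genes), such as Cox8a (-1.57 ± 0.151). Genes of other cell types fell too: 14 of 24 myelin genes fell and 1 rose adjusted over the list alone (13 and 1 over all genes), and of 25 astrocyte genes 11 fell and 1 rose (9 and 0 over all genes). Adjusted p-values of these 5 lists were 1.55e-20, 1.55e-20, 6.6e-11, 0.000351 and 0.0016, and 0.259, 0.49, 0.509, 0.509 and 0.333 with an estimated correlation.

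The other lists reported for D1 neurons of SPF mice did not pass. Homeostatic microglia genes (1 rose and 4 fell of 15, with C1qb from 3.28 to 0.627 CPM) had an adjusted p of 0.278 and activated-microglia genes (1 rose and 2 fell of 9) 0.477. Neuropeptides and opioid receptors (2 of 13 rose; median 0.06, mean -0.05) and the endocannabinoid system (2 of 17 rose and 1 fell) each had an adjusted p of 0.905. Heat shock genes (1 rose and 5 fell of 19), nuclear long non-coding RNAs (1 rose of 8), cholesterol synthesis genes (2 rose of 22) and glucocorticoid-response genes (6 rose and 3 fell of 16; median 0.02, mean -0.04) had 0.534. Glycolysis (3 rose and 6 fell of 22) and reactive-astrocyte genes (1 fell of 5) had 0.525, and the unfolded protein response (5 rose of 21) had 0.222. GABA receptors and transport (4 rose and 1 fell of 20) had 0.232 and voltage-gated potassium channels (9 rose and 1 fell of 27) 0.122. The value was 0.244 for interferon and MHC class I genes (none of 8). Free RNA of striatal neurons (5 rose and 2 fell of 13) had 0.46, cortical glutamatergic markers (1 rose of 6) 0.419, sex-linked transcripts (none of 6) 0.252, and choroid plexus markers (none of 5; median 0.08, mean -0.07) 0.905. These counts are adjusted over the list alone. In all, 2869 of 13490 genes changed in D1 neurons, 1628 higher and 1241 lower. The count was 1397 without SPF rest 1 and 1626 without SPF exercise 2.

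In D2 neurons of SPF mice more early genes fell than rose. Npas4 fell from 32.4 ± 1.55 to 12.9 ± 3.02 CPM (-1.32 ± 0.206, adjusted p = 4.25e-05), Fosl2 fell by 1.81 ± 0.288 and Gadd45b, which acts in DNA demethylation, by 3.39 ± 0.514. Nr4a1 rose (0.73 ± 0.139), while Arc (-0.64 ± 0.279, adjusted p = 0.111), Fos (-0.60 ± 0.321, 0.205) and Egr1 (0.00 ± 0.186, 0.996) did not pass. Of 23 early genes 2 rose and 10 fell adjusted over the list alone (2 and 8 over all genes; median -0.64). The list's adjusted p was 0.0219, against 0.57 with an estimated correlation and 0.0762 without SPF exercise 1. Late genes rose in 7 of 20 and fell in 1, adjusted over the list alone and over all genes, with Spred1 (1.84 ± 0.109) and Homer1 (0.73 ± 0.107). That list's adjusted p was 0.027, and 0.403 with an estimated correlation. Clock genes rose in 8 of 20 and fell in 1 (adjusted p = 0.00178, and 0.262 with an estimated correlation), and the chaperone genes Hspa8 (-1.35 ± 0.172) and Hsp90aa1 (-1.52 ± 0.249) fell. As in D1 neurons, Dnaja2 (2.57 ± 0.138) and Suds3 (2.18 ± 0.161) rose, Cst3 (-2.30 ± 0.165) and Apoe (-2.24 ± 0.164) fell. Mitochondrially encoded genes (13 of 13) and ribosomal protein genes (64 of 73, adjusted over the list alone, and 58 over all genes) fell with medians of -3.57 and -1.23. In all, 2340 of 12539 genes changed (1292 higher, 1048 lower). The count was 1129 without SPF rest 1 and likewise 1129 without SPF exercise 2.

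**Figure D3:**
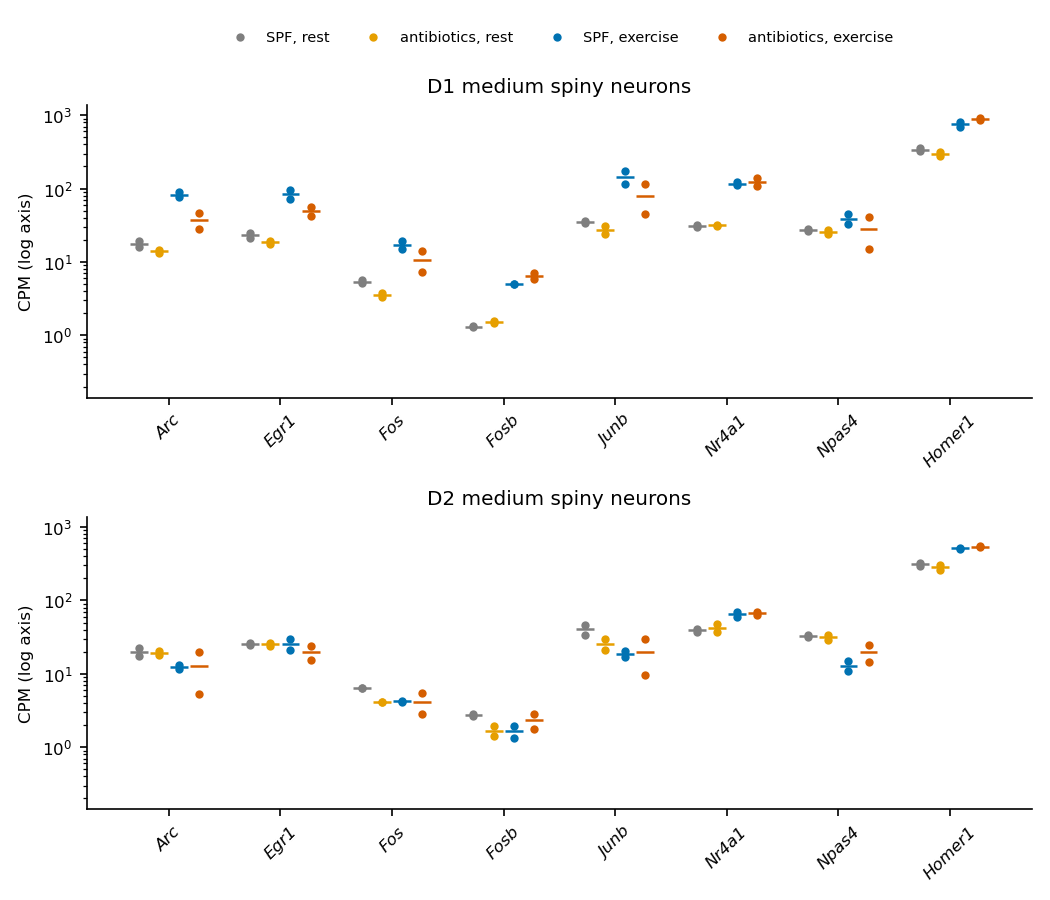
Level (CPM, log axis) of 8 activity-regulated genes in D1 and in D2 neurons of each library, by group; points are libraries and lines are group means. In D1 neurons Arc had a mean of 17.7 CPM in SPF mice at rest, 82.8 CPM in SPF mice after exercise and 37.4 CPM in antibiotic-treated mice after exercise.

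The difference between D1 and D2 neurons of the same libraries was tested in 1 fit of both classes, a test chosen after the data had been seen. In SPF mice the signed exercise effect was higher in D1 neurons for 23 of 25 early genes adjusted over the list alone (17 over all genes). The median difference was 1.81. It was higher for 20 of 25 (11 over all genes) in antibiotic-treated mice, with a median of 1.43. A positive difference can come from a rise in D1 neurons, a fall in D2 neurons or both. As given above, more early genes fell than rose in D2 neurons of SPF mice, among them Gadd45b and Fosl2. In SPF mice the difference was 2.82 ± 0.2 for Arc and 3.13 ± 0.145 for Junb, and in antibiotic-treated mice 2.02 ± 0.245 and 1.91 ± 0.184. With an estimated correlation the list's adjusted p was 0.0488 in SPF and 0.0678 in antibiotic-treated mice.

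**Figure D4:**
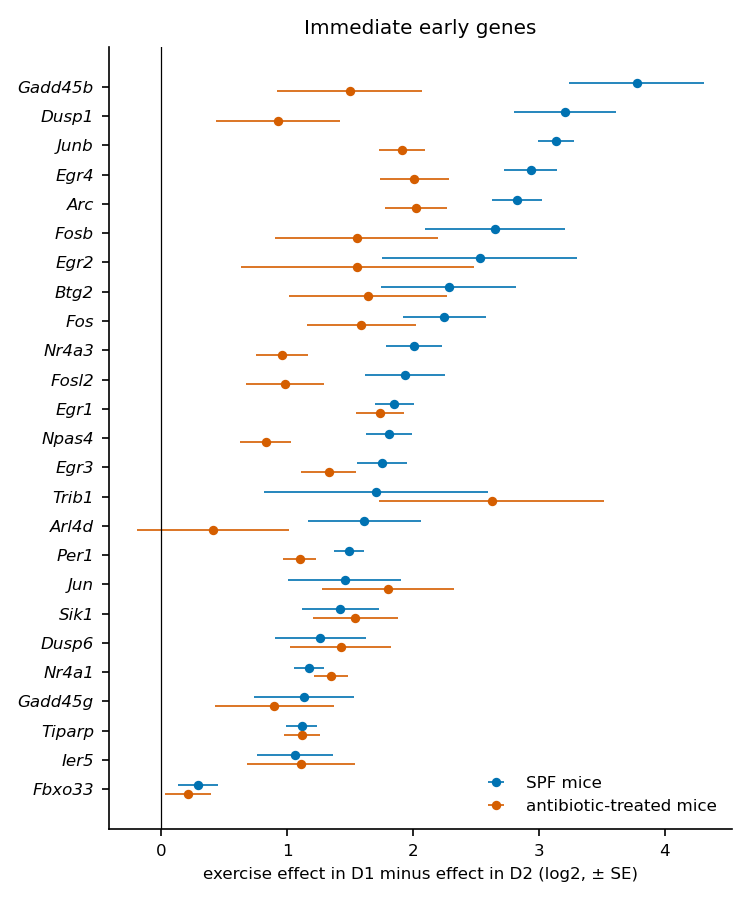
Exercise effect in D1 neurons minus that in D2 neurons (log2, with its SE as bars) for the 25 immediate early genes tested, in SPF and in antibiotic-treated mice. The medians over the genes are 1.81 and 1.43. Values above 0 mean a more positive effect in D1 neurons, through a rise there, a fall in D2 neurons or both.

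Astrocytes of SPF mice gained transcripts of the glucocorticoid response after exercise and lost those of cholesterol synthesis. Fkbp5, a co-chaperone of the glucocorticoid receptor, rose from 2.97 ± 1.82 to 141 ± 42.6 CPM (5.41 ± 0.392, adjusted p = 8.43e-15), and the transcription factor genes Zbtb16 (2.85 ± 0.2), Hif3a (1.78 ± 0.165) and Klf9 (1.59 ± 0.159) rose with it. Of 23 glucocorticoid-response genes 15 rose and 1 fell adjusted over the list alone (14 and 1 over all genes; median 1.14; adjusted p = 6.6e-09, and 0.257 with an estimated correlation). Hmgcs1, which makes the precursor of mevalonate, fell from 129 ± 0.688 to 23 ± 13.4 CPM. In the cholesterol list 18 of 22 fell (15 over all genes; median -1.50; adjusted p = 4.26e-11, and 0.257 with an estimated correlation). Among astrocyte functions 10 of 31 rose (8 over all genes), such as the glutamate transporter gene Slc1a2 (0.90 ± 0.111), glutamine synthetase, Glul (1.01 ± 0.127), and the glucose transporter gene Slc2a1 (1.51 ± 0.305). The adjusted p was 0.0212, and 0.57 with an estimated correlation. In the same libraries transcripts of neurons fell in astrocyte nuclei: 10 of 13 free-RNA genes fell and 1 rose adjusted over the list alone (9 and 1 over all genes; adjusted p = 0.000157, and 0.257 with an estimated correlation). Pde10a rose (2.42 ± 0.158). Ribosomal protein genes fell in 54 of 67 (45 over all genes). In all, 1114 of 10469 genes changed (701 higher, 413 lower), with 637 without SPF rest 1, 550 without SPF exercise 1 and 675 without SPF exercise 2.

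Oligodendrocytes of SPF mice gained transcripts of the glucocorticoid response too. Gli2, a transcription factor of hedgehog signalling, rose from 1.22 ± 0.445 to 127 ± 34.4 CPM (6.52 ± 0.414, adjusted p = 5.63e-16). Fkbp5 rose from 15.6 ± 9.32 to 327 ± 71.5 CPM (4.33 ± 0.235), and Zbtb16 (3.26 ± 0.164), Errfi1, an inhibitor of EGF receptor signalling (3.40 ± 0.223), and the kinase gene Sgk3 (2.81 ± 0.167) rose as well. The lipid-droplet gene Plin4 rose by 5.26 ± 0.416, and by 9.40 without SPF rest 2. The 9.40 rests on 1 SPF rest library and is not read as a larger effect. Of 21 genes of the list 18 rose and 2 fell adjusted over the list alone (16 and 1 over all genes; median 2.01; adjusted p = 7.21e-12, and 0.262 with an estimated correlation). Myelin genes went both ways, with 3 higher and 7 lower of 29 (3 and 6 over all genes; adjusted p = 0.783): Nfasc rose by 0.73 ± 0.123 and Opalin fell by 1.55 ± 0.18. Neuronal free-RNA transcripts fell in 12 of 13 (11 over all genes; median -1.12; adjusted p = 9.4e-08, and 0.242 with an estimated correlation), and ribosomal protein genes in 61 of 67 (59 over all genes). In all, 1779 of 9352 genes changed (949 higher, 830 lower), with 1060 without SPF rest 1, 1180 without SPF rest 2 and 1159 without SPF exercise 2.

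**Figure D5:**
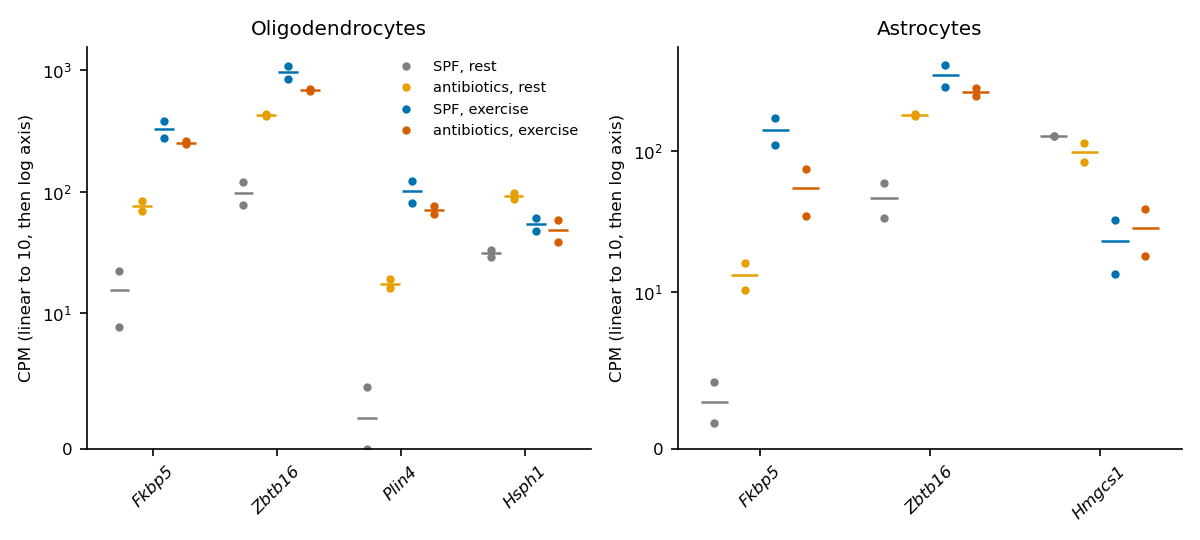
Level (CPM, linear to 10 and logarithmic above) of Fkbp5, Zbtb16, Plin4 and Hsph1 in oligodendrocytes and of Fkbp5, Zbtb16 and Hmgcs1 in astrocytes of each library, by group; points are libraries and lines are group means. In oligodendrocytes the mean of Fkbp5 was 15.6 CPM in SPF mice and 76.5 CPM in antibiotic-treated mice at rest, and 327 and 252 CPM after exercise.

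In microglia, the smallest class with 65 to 130 nuclei per library, Fkbp5 rose from 278 ± 39.6 to 1840 ± 301 CPM (2.73 ± 0.248, adjusted p = 1.89e-14). Zfp36l2, which destabilises messenger RNA, rose by 3.78 ± 0.811 and F13a1, a marker of perivascular macrophages, by 3.71 ± 0.424. None of 23 homeostatic microglia genes passed adjusted over the list alone or over all genes (median -0.28; adjusted p = 0.135), and of 7 activated-microglia genes only Apoe fell (-1.33 ± 0.374; the list's adjusted p = 0.139). The Apoe call ended without SPF rest 1 (-1.06, adjusted p = 0.281), SPF exercise 1 (-1.25, 0.251) or SPF exercise 2 (-1.38, 0.195). All 10 tested mitochondrially encoded genes fell (median -3.34), and this list passed with an estimated correlation as well (adjusted p = 0.0296). In all, 96 of 2557 genes changed (37 higher, 59 lower), with 52 without SPF rest 1, 40 without SPF exercise 1 and 48 without SPF exercise 2.

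Exercise in antibiotic-treated mice raised early genes in D1 neurons too. Nr4a1 rose from 31.5 ± 1.1 to 123 ± 22.2 CPM (1.97 ± 0.13, adjusted p = 3.4e-11), Tiparp by 1.97 ± 0.114, Egr3 by 1.55 ± 0.182, Egr1 by 1.42 ± 0.168 and Arc by 1.44 ± 0.191. Junb rose by 1.55 ± 0.254 and Fos by 1.62 ± 0.298, with 0.69 and 1.05 without antibiotics exercise 1. Of 25 early genes 18 rose adjusted over the list alone and 17 over all genes (median 1.42; adjusted p = 1.17e-09, and 0.406 with an estimated correlation), and Npas4 did not pass (0.15, adjusted p = 0.714). Leaving out antibiotics exercise 1 gave -0.77 for Npas4 (adjusted p = 0.0268) and leaving out antibiotics exercise 2 gave 0.67 (0.0185). Late genes rose in 13 of 22 (11 over all genes; adjusted p = 6.25e-08, and 0.151 with an estimated correlation), with Homer1 (1.56 ± 0.114) and Spred1 (1.57 ± 0.122). Cnr1 (chromosome 4, 33924593 to 33948831), the cannabinoid receptor CB1, rose from 259 ± 87.8 to 424 ± 79.9 CPM (0.72 ± 0.16, adjusted p = 0.00206). The call ended without antibiotics rest 2 (0.39, adjusted p = 0.0854) or antibiotics exercise 1 (0.51, 0.0676), and the value was 1.12 without antibiotics rest 1. Maoa (chromosome X, 16619698 to 16687818) rose by 0.70 ± 0.217 (adjusted p = 0.0216), which ended without antibiotics rest 2 (0.62, 0.149), exercise 1 (0.71, 0.0828) or exercise 2 (0.70, 0.0958).

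Beside these genes, all 13 mitochondrially encoded genes fell in D1 neurons of antibiotic-treated mice (median -3.66), as did 65 of 75 ribosomal protein genes adjusted over the list alone (62 over all genes; median -1.51) and 57 of 71 genes of oxidative phosphorylation, while 1 rose (51 and 0 over all genes). Ina, a neurofilament gene (2.36 ± 0.153), Pdp1 (2.23 ± 0.13) and Irs2, an adaptor of insulin signalling (2.00 ± 0.204), rose, and the ubiquitin gene Ubb (-2.39 ± 0.25) and Cst3 (-2.15 ± 0.148) fell. In all, 2882 of 13490 genes changed (1553 higher, 1329 lower), with 1461 without antibiotics rest 2, 1913 without antibiotics exercise 1 and 1498 without antibiotics exercise 2. In D2 neurons 3 of 23 early genes rose and 3 fell, adjusted over the list alone and over all genes (adjusted p = 0.609), with Tiparp at 0.86 ± 0.164. Heat shock genes fell in 10 of 19 D2 genes on both counts (median -0.54; adjusted p = 0.0145, and 0.585 with an estimated correlation), such as Hspa8 (-1.48 ± 0.175) and Hsp90ab1 (-1.13 ± 0.145), and ribosomal protein genes fell in 67 of 73 (58 over all genes). In D2 neurons 2384 of 12539 genes changed (1309 higher, 1075 lower), with 1161 without antibiotics rest 2, 1550 without antibiotics exercise 1 and 1070 without antibiotics exercise 2.

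Astrocytes of antibiotic-treated mice also gained glucocorticoid-response and lost cholesterol transcripts after exercise. Fkbp5 rose from 13.3 ± 4.15 to 54.9 ± 28.5 CPM (1.95 ± 0.354), Hif3a by 1.08 ± 0.155 and Klf9 by 0.93 ± 0.154, with 7 of 23 glucocorticoid-response genes higher and 2 lower adjusted over the list alone (6 and 1 over all genes; adjusted p = 0.00531, and 0.432 with an estimated correlation). Cholesterol genes fell in 17 of 22 (15 over all genes; median -1.08; adjusted p = 4.34e-09, and 0.266 with an estimated correlation), with Sqle at -2.09 ± 0.316 and Hmgcs1 at -1.68 ± 0.243. Neuronal free-RNA transcripts fell in 12 of 13 astrocyte genes and 1 rose on both counts (adjusted p = 8.7e-09, and 0.123 with an estimated correlation). In oligodendrocytes Errfi1 (2.73 ± 0.232), Gli2 (2.53 ± 0.307), Fkbp5 (1.73 ± 0.197) and Sgk3 (1.38 ± 0.168) rose, and 13 of 21 glucocorticoid-response genes rose and 1 fell (12 and 1 over all genes; adjusted p = 6.93e-05, and 0.388 with an estimated correlation). Heat shock genes fell in 10 of 20 (8 over all genes; adjusted p = 0.00322, and 0.419 with an estimated correlation), as did all 13 free-RNA genes and 63 of 67 ribosomal protein genes (59 over all genes). In astrocytes 1680 genes changed (786 higher, 894 lower), with 807 without antibiotics rest 2 and 650 without antibiotics exercise 2. In oligodendrocytes 1704 changed (760 higher, 944 lower), with 879 without antibiotics rest 2, 1117 without antibiotics exercise 1 and 1071 without antibiotics exercise 2. In microglia 150 changed (36 higher, 114 lower), 85 without antibiotics exercise 1. All 10 mitochondrially encoded genes fell (median -4.16; adjusted p = 0.0273 with an estimated correlation). Fkbp5 did not pass (0.31, adjusted p = 0.507), and F13a1, with no count at rest, was at least 7.06-fold higher after exercise against a floor of 3 counts over the group.

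Both exercise effects, which share no library, called many of the same genes. In D1 neurons 990 genes were higher in both against 187 for independent lists and 679 lower in both against 122. In all, 8 of the 1677 shared genes went opposite ways. In D2 neurons the counts were 734 higher (135 by chance) and 543 lower (89.8), in astrocytes 363 (52.6) and 283 (35.3), in oligodendrocytes 459 (77.1) and 497 (83.8). In microglia they were 10 (0.521) and 35 (2.63). Both effects came from the same fit, and both set exercise against rest libraries that differ in RNA composition. The shared calls therefore do not tell exercise from that difference.

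Antibiotics at rest changed fewer genes, and several of them in both kinds of projection neuron. The rest libraries of antibiotic-treated mice also held more Gm42418 and less Hbb-bs than those of SPF mice, as given above, and fewer UMIs per nucleus, with medians of 3890 and 4170 against 5128 and 5126 in D1 neurons. Ubash3b, a phosphatase gene, rose in D1 neurons from 25.4 ± 3.99 to 56.0 ± 3.28 CPM (1.14 ± 0.133, adjusted p = 2.39e-05), and the potassium channel gene Kcnk13 (chromosome 12, 99964499 to 100062682) and Acot7 (chromosome 4, 152178134 to 152271855), which cleaves long-chain acyl-CoA, rose by 0.92 ± 0.118 and 0.91 ± 0.133. In D2 neurons Acot7 rose by 0.96 ± 0.136 and Ubash3b by 0.88 ± 0.137. Cnr1 was lower in both, with 418 ± 65.6 against 259 ± 87.8 CPM in D1 neurons (-0.70 ± 0.158, adjusted p = 0.028) and 402 ± 61 against 243 ± 58 CPM in D2 neurons (-0.73 ± 0.13, adjusted p = 0.00675). Its D1 call ended without antibiotics rest 2 (-0.37, adjusted p = 0.24) or SPF rest 1 (-0.52, 0.65) and grew to -1.09 without antibiotics rest 1, and its D2 call ended without antibiotics rest 2 (-0.49, 0.0563) or SPF rest 1 (-0.57, 0.423). The D2 call of Ubash3b ended without SPF rest 1 (0.71, adjusted p = 0.146). Maoa fell in D1 neurons adjusted over the dopamine list alone (-0.67 ± 0.192, adjusted p = 0.0206; 11.6 ± 0.33 against 7.34 ± 0.474 CPM) and not over all genes (0.0923), and the other 10 tested genes of that list did not pass (the list's adjusted p = 0.0564).

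Heat shock genes rose in D1 neurons with antibiotics at rest in 6 of 19 adjusted over the list alone (2 over all genes; median 0.25; adjusted p = 0.0106, and 0.482 with an estimated correlation), and in D2 neurons in 2 (1 over all genes; adjusted p = 0.0152, and 0.669 with an estimated correlation). Hsph1, a chaperone of the Hsp110 family, rose by 0.81 ± 0.151 in D1 and 0.83 ± 0.139 in D2 neurons. Without SPF rest 1 the calls ended (0.62 with adjusted p = 0.333, and 0.77 with 0.146), and the D1 call also ended without antibiotics rest 2 (0.64, 0.0651). Clock genes rose in 2 of 21 in D1 neurons (1 over all genes; adjusted p = 0.00865, and 0.493 with an estimated correlation), with Per2 at 0.88 ± 0.142, a call that ended without SPF rest 1 (0.71, adjusted p = 0.137). In D2 neurons 5 of 26 potassium channel genes rose and 2 fell adjusted over the list alone (1 and 0 over all genes), led by Kcnn3 (0.63 ± 0.111, adjusted p = 0.00675; 0.59 and 0.2 without SPF rest 1). In D1 neurons 139 of 13490 genes changed (73 higher, 66 lower), with 18 without SPF rest 1, 61 without SPF rest 2 and 210 without SPF exercise 1. In D2 neurons 63 of 12539 changed (31 higher, 32 lower), with 6 without SPF rest 1, 98 without antibiotics rest 1 and 113 without antibiotics rest 2. Of the genes tested in both, 137 were called in D1 and 63 in D2 neurons, and 46 were called in both with the same direction. The same libraries gave both classes, so the calls are not independent.

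In glia some glucocorticoid-response genes were higher with antibiotics at rest, where the median UMIs of oligodendrocytes were 1081 and 1169 against 1391 and 1354 in SPF mice. Zbtb16 (chromosome 9, 48654297 to 48836222) rose in oligodendrocytes from 98.4 ± 29.6 to 426 ± 13.5 CPM (2.10 ± 0.167, adjusted p = 5.48e-12) and in astrocytes from 46.6 ± 18.4 to 180 ± 4.05 CPM (1.89 ± 0.194, adjusted p = 1.21e-08). Fkbp5 (chromosome 17, 28399094 to 28517527) rose in oligodendrocytes (2.23 ± 0.283, adjusted p = 2.47e-06) and microglia (1.81 ± 0.256, adjusted p = 1.09e-06), and in astrocytes only adjusted over the list alone (1.96 ± 0.566, adjusted p = 0.00892 and 0.122 over all genes). In oligodendrocytes 11 of 21 genes of the list rose and 1 fell adjusted over the list alone (4 and 0 over all genes; median 0.54; adjusted p = 3.17e-08, and 0.556 with an estimated correlation), among them the kinase gene Sgk1 (1.22 ± 0.194; 0.88 with adjusted p = 0.148 without SPF rest 1). Heat shock genes rose in 11 of 20 (4 over all genes; median 0.67; adjusted p = 6.67e-07, and 0.556 with an estimated correlation), with Hsph1 from 31.2 ± 3 to 92.6 ± 7.22 CPM (1.58 ± 0.233). In astrocytes 5 of 23 glucocorticoid-response genes rose (2 over all genes; adjusted p = 0.00992, and 0.756 with an estimated correlation). Of 22 cholesterol genes 5 fell (1 over all genes; adjusted p = 0.00724, and 0.756 with an estimated correlation). The glycolytic enzyme gene Pfkp (1.01 ± 0.157) and the anion channel gene Lrrc8c (from 55.4 to 139 CPM) rose. The counts were 60 in astrocytes (46 higher, 14 lower; 25 without antibiotics rest 2, 11 without SPF rest 1, 37 without SPF rest 2), 43 in oligodendrocytes (32 higher, 11 lower; 20 without antibiotics rest 2, 10 without SPF rest 1) and 6 in microglia (5 higher, 1 lower; 14 without antibiotics rest 2, 13 without SPF rest 2, 17 and 16 without antibiotics exercise 1 and 2, 12 without SPF exercise 1 or 2). Scaled with RLE size factors, 100% of the microglia calls were higher in place of 83.3%.

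Antibiotics after exercise left little that passed. In D1 neurons Arc was lower in antibiotic-treated mice, with 37.4 ± 13.2 against 82.8 ± 9.59 CPM (-1.14 ± 0.165, adjusted p = 0.00456), the only one of 13490 genes called, with 853 at an unadjusted p under 0.05. The count was 3 without antibiotics rest 1 or 2, 12 without antibiotics exercise 1 and 57 without SPF exercise 2. The call ended without antibiotics exercise 2 (-0.82, adjusted p = 0.164). Of 25 early genes 2 were higher and 6 lower adjusted over the list alone, among them Egr1 (-0.79 ± 0.15, adjusted p = 0.107 over all genes), Junb (-0.84 ± 0.23, 0.526) and, higher, Nr4a3 (0.95 ± 0.191, 0.132). That list had a median of -0.44 and an adjusted p of 0.0269, against 0.905 with an estimated correlation and 0.984 without antibiotics exercise 2. Homer1 (0.22 ± 0.111, adjusted p = 0.797) and Npas4 (-0.46 ± 0.239, 0.8) did not pass. In D2 neurons edgeR and DESeq2 called no gene, with 666 at an unadjusted p under 0.05 in edgeR. Without antibiotics exercise 1 there were 10 calls and without antibiotics exercise 2 there was 1. The lowest p-values were those of Aspa (3.59 ± 0.782, adjusted p = 0.74) and Nr4a3 (1.39 ± 0.306, 0.74). Myelin genes in D2 nuclei had a median of 0.62 (1 of 21 higher adjusted over the list alone; adjusted p = 4.16e-05, and 0.901 with an estimated correlation).

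After exercise a few glucocorticoid-response genes of astrocytes and oligodendrocytes were lower with antibiotics. In microglia 1 of 5 was lower adjusted over the list alone and 0 over all genes (adjusted p = 0.914 for the list). Fkbp5 in astrocytes was at 54.9 ± 28.5 against 141 ± 42.6 CPM (-1.49 ± 0.269, adjusted p = 0.0115), with 7 of 23 genes of the list lower adjusted over the list alone (1 over all genes; adjusted p = 0.00476, and 0.952 with an estimated correlation). The Fkbp5 call ended without antibiotics exercise 2 (-0.93, 0.747) or SPF exercise 1 (-1.10, 0.733). In oligodendrocytes 6 of 21 were lower (1 over all genes; adjusted p = 0.0067, and 0.781 with an estimated correlation). Sgk3 passed (-0.84 ± 0.151, adjusted p = 0.0153), a call that ended without antibiotics exercise 2 (-0.85, 0.0609) or SPF exercise 1 (-0.52, 0.86). Astrocytes had 3 calls by edgeR (1 without antibiotics exercise 2 or SPF exercise 1, 6 without SPF exercise 2) and 0 by DESeq2. Oligodendrocytes had 2 by edgeR (5 without antibiotics rest 1 or 2, 9 and 4 without antibiotics exercise 1 and 2, 0 and 22 without SPF exercise 1 and 2) and 0 by DESeq2. At an unadjusted p under 0.05 there were 657 and 576 genes. Microglia had 6 calls, 1 without SPF exercise 1. Among them the astrocyte genes Slc1a2 (3.75 ± 0.509, adjusted p = 5.69e-07) and Gpc5 (4.85 ± 0.912) were higher, in libraries whose astrocyte share was 10.0% and 18.6% against a mean of 5.68% in SPF mice. Without SPF exercise 1 Slc1a2 stood at 8.87 and Gpc5 at 3.98, where the Gpc5 call ended. Without SPF exercise 2 Gpc5 stood at 7.80, against 1 SPF exercise library with no count, so 7.80 has no measured size. The 8.87 also rests on 1 SPF exercise library and is not read as a larger effect.

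The difference of both exercise effects was tested directly and was negative for part of the glucocorticoid-response genes of oligodendrocytes and astrocytes: exercise raised them less in antibiotic-treated mice. Zbtb16, Fkbp5 and Sgk1 of oligodendrocytes were already higher with antibiotics at rest, as given above. A negative difference may thus come from the level at rest as well as from that after exercise. In oligodendrocytes the difference was -2.58 ± 0.219 for Zbtb16 (adjusted p = 5.26e-11), -1.88 ± 0.267 for Sgk1 and -1.43 ± 0.237 for Sgk3, with 14 of 21 genes of the list lower and 1 higher adjusted over the list alone (6 and 0 over all genes; median -1.21; adjusted p = 8.72e-09, and 0.374 with an estimated correlation). In astrocytes 8 of 23 were lower (3 over all genes; median -0.65; adjusted p = 5.03e-05, and 0.621 with an estimated correlation). In D1 neurons the difference was -0.78 ± 0.253 for Arc (adjusted p = 0.331), 0.61 ± 0.224 for Cnr1 (0.434) and 0.52 ± 0.284 for Maoa (0.65), none of which passed. The early gene list had a median of -0.34 (none of 25 genes passed; adjusted p = 0.0851, and 0.000286 without antibiotics exercise 1). In D2 neurons the early gene list had a median of 0.44 (2 of 23 higher adjusted over the list alone, none over all genes; adjusted p = 0.048, 0.676 with an estimated correlation and 0.891 without antibiotics exercise 1).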

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

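The tests of the D1-minus-D2 difference, of nuclei with under 0.1% mitochondrial UMIs of the clock-gene score and inside single D1 or oligodendrocyte clusters were chosen after the results they bear on had been seen; thinning and leaving out libraries were planned. The differences given in the next 3 paragraphs, and that of the early genes between D1 and D2 neurons, stand here because the exercise effect differed between antibiotic-treated and SPF mice or between both neuron types by a test of the difference itself. The glucocorticoid-response genes at rest and Arc and Egr1 after exercise are weighed for their interest alone.

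The exercise effect differed between antibiotic-treated and SPF mice for 6 genes in D1 neurons (26 without antibiotics rest 1, 36 without antibiotics exercise 1, 11 without SPF exercise 1, 20 without SPF exercise 2) and 5 in D2 neurons (39 without antibiotics rest 1, 28 without antibiotics exercise 1, 3 without antibiotics rest 2 or SPF exercise 1, 2 without SPF rest 1, SPF rest 2 or antibiotics exercise 2, 1 without SPF exercise 2). It differed for 30 in astrocytes (9 without SPF rest 1, 19 without antibiotics exercise 1, 15 without antibiotics exercise 2 or SPF exercise 1, 48 without SPF exercise 2), 37 in oligodendrocytes (12 without SPF rest 1, 24 without SPF exercise 1, 60 without SPF exercise 2) and 9 in microglia (18 without SPF rest 2, 4 without SPF exercise 1). The difference was -1.003 for the potassium channel gene Kcnk13 in D1 neurons (-0.95 with adjusted p = 0.0966 without SPF rest 1). For Acot7 in D2 neurons it was -1.09 (adjusted p = 0.0355), and no call was left without antibiotics rest 2 (adjusted p = 0.069), SPF rest 1 (0.219), SPF rest 2 (0.105), antibiotics exercise 1 (0.0747), antibiotics exercise 2 (0.124) or SPF exercise 2 (0.176).

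In astrocytes the difference was -2.28 for Zbtb16 and -3.46 for Fkbp5 (adjusted p = 0.0653 without antibiotics rest 1). It was 2.65 for the transporter gene Slco1b2 (adjusted p = 0.112 without antibiotics rest 2, 0.167 without SPF rest 2, 0.0727 without SPF exercise 1) and 1.84 for Ccdc34 (0.0663 without antibiotics exercise 1, 0.175 without SPF exercise 1). For the peroxisomal gene Pxmp2 it was 1.39 (adjusted p = 0.128 without antibiotics rest 1, 0.191 without SPF rest 1, 0.101 without antibiotics exercise 1, 0.0995 without antibiotics exercise 2, 0.246 without SPF exercise 1). In oligodendrocytes the difference for Plin4 was -3.28. Without SPF rest 1 it was -2.43 and the call ended, and without SPF rest 2 it was -7.42. The -7.42 rests on 1 SPF rest library and is not read as a larger effect. The difference was -3.99 for Gli2 (chromosome 1, 118834132 to 119053619) and -2.60 for Fkbp5. It was 1.31 for Luzp2 (adjusted p = 0.0758 without antibiotics rest 2, 0.271 without SPF rest 1, 0.513 without antibiotics exercise 2, 0.0941 without SPF exercise 2) and 1.03 for Son, a splicing factor gene (0.107 without SPF rest 1, 0.0879 without SPF rest 2, 0.409 without antibiotics exercise 2, 0.0913 without SPF exercise 1).

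In microglia the difference was -2.41 for Fkbp5, -2.64 for the actin regulator gene Phactr1 and -2.76 for the potassium channel gene Kcnq5 (-1.98 with adjusted p = 0.331 without antibiotics exercise 1, -0.67 with 0.951 without SPF exercise 1). It was 6.66 for Gpc5, 4.25 for Slc1a2 (9.37 without SPF exercise 1) and 5.63 for Luzp2, all 3 of them genes that astrocytes express. The 9.37 rests on 1 SPF exercise library and is not read as a larger effect. The Luzp2 call was lost without SPF rest 1 (adjusted p = 0.973), antibiotics exercise 2 (0.0871), SPF exercise 1 (0.0653) or SPF exercise 2 (0.177). Gpc5 in microglia lay at 445 and 340 CPM in the antibiotic-treated exercise libraries, 0 and 23.6 CPM in the SPF exercise libraries, 91.5 and 71.2 CPM in antibiotic-treated mice at rest and 517 and 83.3 CPM in SPF mice at rest.

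Immediate early genes were higher after exercise in D1 neurons and not as a list in D2 neurons of the same libraries (medians of -0.64 in SPF and -0.33 in antibiotic-treated mice), with a median D1-minus-D2 difference of 1.81 in SPF and 1.43 in antibiotic-treated mice (adjusted p = 0.0488 and 0.0678 with an estimated correlation, and 0.282 and 0.406 for D1 neurons alone). Less cytoplasmic RNA in the exercise nuclei was weighed in nuclei under 0.1% mitochondrial UMIs. There the 19 members that rose in SPF mice had a median of 1.93 and a lower quartile of 1.56, against a median of 1.76 in all nuclei (2.29 and 1.97 for the 10 most changed). Such nuclei numbered 58 and 89 in the SPF rest and 1252 and 1227 in the SPF exercise libraries. The rise was thus kept against rest nuclei under the cut, but this cause cannot be set aside. The members were picked for their rise in the same sums. The cut does not match rest nuclei to the SPF exercise libraries, whose medians were 0.0278% and 0.0243%. Of the 19, Jun, Fosb, Dusp6 and Dusp1 had smaller values under that cut (1.23, 1.34, 1.63 and 1.64). Egr2 and Trib1 had far larger ones (7.02 and 7.06, against 1.92 and 3.34 in all nuclei). That fit had few rest nuclei and no low-count filter, so the values of Egr2 and Trib1 are not read as larger effects. A different preparation of the rest and exercise libraries cannot be told apart from exercise, since every exercise library differs from every rest library in RNA composition, and the D1-minus-D2 difference of 1.81 shows only that it would have to act on both neuron types unequally. That exercise activates D1 more than D2 neurons stays a hypothesis, untested here against rest libraries prepared alike.

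Glucocorticoid-response genes were higher at rest in oligodendrocytes of antibiotic-treated mice, with a median of 1.22 over the 11 members that rose and 0.54 over all 21 (4 passed over all genes; adjusted p = 0.556 for the list with an estimated correlation). A different mix of oligodendrocyte clusters is argued against by the split of the nuclei, which was alike in both groups. With antibiotics at rest cluster 2 held 452 and 561 nuclei and cluster 9 held 199 and 220. In SPF mice at rest they held 496 and 636, and 227 and 255. The medians of the members were 1.09 and 1.48 inside these 2 large clusters, but the members were picked for their rise in the same sums. A difference in depth cannot be told apart. The median was 1.22 after thinning, but thinning the sums leaves the expected share of each gene as it was. It does not act on the UMIs per nucleus. The higher Gm42418 and lower Hbb-bs of the antibiotic-treated rest libraries leave a difference in their preparation open, which was not tested. A different time of day at collection cannot be told apart: the night-minus-day score of clock genes differed by -0.24 between the rest groups in oligodendrocytes, -0.08 in D1 neurons and 0.035 in D2 neurons, and the libraries of both groups overlapped in each. Without Per1 and Per2 the groups were apart in D1 neurons (-0.22) and overlapped in D2 neurons (-0.04) and oligodendrocytes (-0.3). A higher level of corticosterone in antibiotic-treated mice at rest, through stress, handling or the flora itself, may also raise these genes and was not tested.

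After exercise Arc was lower in D1 neurons of antibiotic-treated mice, and Egr1 was at -0.79 without passing over all genes (adjusted p = 0.107). A different mix of D1 clusters is argued against by the nuclei per cluster, which were split much alike. Clusters 0, 5, 6 and 8 held 500, 201, 198 and 146, and 467, 210, 187 and 184, in the antibiotic-treated exercise libraries. In the SPF exercise libraries they held 605, 249, 251 and 223, and 634, 247, 228 and 184. The mean change inside the clusters was -1.10 for Arc and -0.76 for Egr1, but both genes were taken up after the same sums had been seen. A shift of whole libraries that all neurons share cannot be set aside. A fall of Arc was not seen in D2 neurons (0.044). In the fit of both classes its D1-minus-D2 difference was -1.17 (unadjusted p = 2.87e-05, adjusted p = 0.129 over all genes). Arc was the only gene called in D1 neurons, a choice that favours a large difference, and none of 13465 genes passed in that fit. For Egr1 the difference was -0.46 (unadjusted p = 0.0179, adjusted p = 0.831). Egr1 stood at -0.33 in D2 neurons, so that part of its change may be shared. A single exercise library cannot be told apart, as Arc stood at -0.82 without antibiotics exercise 2 (adjusted p = 0.164) and at -1.01, -1.56 and -1.25 without each of the other exercise libraries. A weaker response of D1 neurons without the flora, or a shorter or later bout of exercise, may each lower Arc, and neither was tested.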

How the results depend on the processing

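All tests behind the values in this part were planned. The directions of exercise and of antibiotics at rest held for most named genes, and the number of genes called depended strongly on the tool and on single libraries. Of 489 results for named genes 307 were called. Called results that lost the call numbered 65 with DESeq2, 1 with RLE size factors, 10 with doublets kept (1 of them reversed), 3 with no low-count filter, 4 with the replicate block, 21 of 298 in sums thinned to the lowest total, and 15 to 49 when 1 library was left out. Of 182 results not called, 2 passed with DESeq2, 0 with RLE size factors, 2 with doublets kept, 25 with no low-count filter, 6 with the block, 5 after thinning and 0 to 15 when 1 library was left out, where 1 more reversed. With 1 library left out, the lone library of its group is taken to vary like the other groups. RLE size factors changed the share of higher calls only for antibiotics at rest in microglia. Of 20 class shares 16 moved at a minimum of 1000 UMIs, 6 at the higher clustering resolution and 6 with doublets kept. Moved means that the group mean shifted by at least the SD of its 2 libraries. That SD was 0.001 for D2 neurons with antibiotics at rest and 6.06 for astrocytes with antibiotics after exercise. These counts are thus no measure of the size of the shifts. Of the 5 classes microglia had the least depth, with 54041 to 149619 UMIs per library against 4786467 to 11665534 in D1 neurons. Where a value below differs, the cause was not tested.

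With DESeq2 the counts for exercise in SPF mice were 1803 in D1 neurons (1791 of them called by edgeR too), 1394 in D2 neurons, 578 in astrocytes, 762 in oligodendrocytes and 20 in microglia. For exercise in antibiotic-treated mice they were 1893, 1432, 598, 689 and 36. For antibiotics at rest they were 39 in astrocytes, 21 in oligodendrocytes and 2 in microglia, for antibiotics after exercise 0, 0 and 1, and for the difference of the exercise effects 21 in D1 neurons, 16 in D2 neurons, 23 in oligodendrocytes and 4 in microglia.

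With no low-count filter antibiotics at rest gave 312 genes in D1 neurons, 203 in D2 neurons, 65 in oligodendrocytes and 15 in microglia. Antibiotics after exercise gave 40 in D1 neurons, 10 in D2 neurons, 9 in astrocytes and 7 in oligodendrocytes, and the difference of the exercise effects gave 59 in D1 neurons, 59 in D2 neurons and 57 in oligodendrocytes. Without the filter many more genes of low counts were tested. No label pairs the libraries by replicate number. Correlations of the same number's deviations among SPF rest, SPF exercise and antibiotics exercise ran from 0.23 to 0.265 in D1 neurons and 0.113 to 0.202 in D2 neurons, and those with antibiotics rest from -0.285 to -0.154 and -0.302 to -0.077. Used as a block, the numbers gave 3 genes in place of 1 for antibiotics after exercise and 21 in place of 6 for the difference in D1 neurons, and 5 in place of 2 for antibiotics after exercise in oligodendrocytes, and moved no other count by over 1.5 times.

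Sums thinned to the lowest total gave 2 genes for antibiotics after exercise in D1 neurons, 8 for the difference in D2 neurons, 653, 34 and 6 in astrocytes for exercise in antibiotic-treated mice, antibiotics at rest and antibiotics after exercise, and 80 and 10 in microglia for exercise in antibiotic-treated mice and antibiotics after exercise. With doublets kept there were 21 genes for antibiotics after exercise and 77 for the difference in astrocytes, and 76 for exercise in antibiotic-treated mice and 3 for antibiotics at rest in microglia, where Phactr1 at rest turned from 1.00 to -0.01.

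The adjusted p of the immediate early gene list, with an estimated correlation, was 0.282 for exercise in SPF mice, 0.406 for exercise in antibiotic-treated mice and 0.905 for antibiotics after exercise in D1 neurons, and 0.57 for exercise in SPF mice and 0.676 for the difference in D2 neurons. With fry it was 0.766 for antibiotics after exercise in D1 neurons, and 0.135 for exercise in SPF mice and 0.605 for the difference in D2 neurons. With no filter it was 0.379 for antibiotics after exercise in D1 neurons and 0.0856 for the difference in D2 neurons. In D2 neurons it was 0.0503 with doublets kept and 0.0605 after thinning for exercise in SPF mice, and 0.0652 and 0.189 for the difference.

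With each library left out in turn, the counts in D1 neurons ran from 1397 to 3139 for exercise in SPF mice, 1461 to 3015 for exercise in antibiotic-treated mice, 18 to 210 for antibiotics at rest, 1 to 57 for antibiotics after exercise and 5 to 36 for the difference. In D2 neurons they ran in the same order from 1129 to 2705, 1070 to 2476, 6 to 113, 0 to 10 and 1 to 39. In astrocytes they ran from 550 to 1155, 650 to 1787, 11 to 69, 1 to 6 and 9 to 48. In oligodendrocytes they ran from 1060 to 1867, 879 to 1789, 10 to 61, 0 to 22 and 12 to 60, and in microglia from 40 to 111, 85 to 187, 4 to 17, 1 to 8 and 4 to 18. The adjusted p of the early gene list ran from 1.55e-05 to 0.984 for antibiotics after exercise and from 0.000286 to 0.968 for the difference in D1 neurons. In D2 neurons it ran from 0.0128 to 0.0762 for exercise in SPF mice, 4.6e-05 to 0.594 for antibiotics after exercise and 2.54e-05 to 0.891 for the difference. Npas4 in D1 neurons, at 0.15 for exercise in antibiotic-treated mice, ran from -0.77 without antibiotics exercise 1 to 0.67 without antibiotics exercise 2.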

Other observations

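The tests named in this part were planned. Cholinergic interneurons, which release acetylcholine in the striatum, made up 1.92% ± 0.013 (SD, n = 2) of the nuclei in antibiotic-treated mice at rest, 1.13% ± 0.107 in SPF mice at rest, 0.927% in antibiotic-treated and 1.18% in SPF mice after exercise. Sst/Npy interneurons were 0.219 percentage points higher and differentiating oligodendrocytes 0.449 points lower after exercise, each with an exact permutation p of 0.0286 and an adjusted p of 0.114. Of all classes, the smallest p for antibiotics was that of oligodendrocyte precursors, lower by 0.271 points (exact permutation p = 0.0571, adjusted p = 0.816).

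In oligodendrocytes voltage-gated potassium channel genes fell with exercise in antibiotic-treated mice in 12 of 19 and 1 rose adjusted over the list alone (10 and 1 over all genes; median -1.09; adjusted p = 2e-05, and 0.164 with an estimated correlation), and in astrocytes in 11 of 22 with 2 higher (9 and 2 over all genes; median -0.87; adjusted p = 0.00106, and 0.266 with an estimated correlation). Many of these channels are abundant in neurons, and neuronal transcripts fell beside them in both classes: in oligodendrocytes Ddn, a postsynaptic gene, fell by 3.59 ± 0.533 and the kinase gene Camk2a fell by 2.58 ± 0.297, and in astrocytes Adcy5 fell by 2.93 ± 0.314.

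In microglia ribosomal protein genes had a median of 0.68 with antibiotics at rest (6 of 27 higher adjusted over the list alone, 0 over all genes with edgeR, where 6 genes of the class passed; adjusted p = 5.67e-07, and 0.883 with an estimated correlation), led by Rps3 (1.66 ± 0.446, adjusted p = 0.0692). Homeostatic microglia genes did not move as a list there (adjusted p = 0.589).

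Xist, which the inactive X chromosome makes, lay at 1.06 to 1.49 CPM in the rest libraries and 0.466 to 0.751 CPM in the exercise libraries. The Y-linked genes were far higher in every library, with Ddx3y at 36.5 to 50.4 CPM and Uty at 104 to 124 CPM. Slc17a7, a marker of cortical glutamatergic neurons, lay at 1.45 to 12 CPM.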
